A study of Mus musculus with 8 samples.

How the data were processed

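miRNAs were measured in brown adipose tissue, the heat-producing fat depot, of 6 male C57Bl6N mice aged 8 weeks. Of these, 3 mice had been held at 8 °C for 24 h and 3 had stayed at room temperature (21 °C). Total RNA was extracted with Trizol, labelled with the dye Cy3 and hybridised to 1-colour Agilent mouse miRNA arrays, per the labels' protocols. Mouse 1 of the cold group and mouse 4 of the room temperature group were each hybridised to 2 arrays, which gave 8 arrays in all. The arrays lay on 1 slide and were scanned once, per the file headers. All cold samples lay in 1 row of the slide and all room temperature samples in the other, so array row and group cannot be told apart. Mouse numbers were not shared between the groups, and the labels did not pair the mice.

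The deposited files hold 1 array's scanner output each, with the spot intensity on a linear scale in signal units after background subtraction, as the authors' scanner software wrote it. Per the file headers this was Agilent Feature Extraction 10.7.3.1, whereas the submitters' processing notes name Agilent Feature Extraction 9.5.3.1. The authors' deposited value table of the series held the same processed intensities, with no scaling, centring or log transformation: the largest difference from the scanner values was 0 over all 8 columns. Its column medians lay between 1.12 and 1.55 units. The software's background-subtracted total intensity per miRNA, also deposited by the authors, was used for an alternative only.

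Each array held 12493 spots, of which 11540 carried probes for miRNAs and 672 were negative controls. The 1712 miRNA probes were printed in 5 to 20 spots each and covered 566 mouse miRNAs and 10 viral ones. Control spots and spots that the software marked as outliers (between 2.09% and 2.63% of the miRNA spots per array) were left out, and no spot was saturated. Spots of one probe were averaged on the linear scale. Each array was divided by its 75th percentile over the 267 probes (15.6%) that were well above background on all 8 arrays. Values under 0.01 were then set to 0.01, and log2 was taken. A probe was kept when more than 0.5 of its spots were well above background on every array of at least 1 group, which 329 of the 1712 probes (19.2%) met. A miRNA's value was the mean over its kept probes, which left 189 mouse miRNAs. Of 125 miRNAs with several kept probes, 53 had probes whose changes differed in sign, among them none of the 18 such miRNAs that passed the test. miRNA names are those of the array design, which predates the current arm names. Precursor genes, their hosts and their neighbours were looked up by name in a RefSeq gene table of the mouse assembly GRCm38.p6, in which 180 of the 189 miRNAs had a match. The array files name no genome build, so no coordinates are given.

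The arrays of one mouse were averaged before the fit, so that n = 3 mice per group. Cold minus room temperature was tested for each miRNA with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Where a miRNA was not well above background on any array of a group, its fold is given as a bound. The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. Shifts of 22 miRNA lists were tested with limma's camera at a preset correlation of 0.01, 2-sided, for the 17 lists with at least 3 measured members. The same lists were tested by camera with an estimated correlation and by fry. The lists were brown-promoting, brown-restraining, muscle, adipogenic, leukocyte, erythroid, endothelial, stromal and smooth muscle, epithelial, neural and liver miRNAs, and those induced by cAMP or hypoxia. Genomic clusters and families made up the rest: miR-17/92 with its paralogues, let-7, miR-30, miR-29, miR-15/16, miR-23/27/24, miR-221/222, the miR-183 cluster, the Dlk1-Dio3 imprinted cluster and the Sfmbt2 intronic cluster. Values of single measures per mouse were compared with an exact permutation test.

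The groups, the comparison, the lists and the alternatives were fixed before the data were examined, except the 2 alternatives named below. Of the tests of explanations in the closing parts, those of the muscle and Sfmbt2 patterns were chosen only after the result was seen. The rule for named miRNAs, fixed with them, took 5 kinds. These were the 10 miRNAs per direction with the largest change among those past the threshold whose groups of mice did not overlap, the 5 best by p in a direction with too few calls, a set list of muscle and brown fat miRNAs, the 3 members of each list with the smallest p, and the 5 miRNAs with the highest normalised log2 mean over their probes. It named 68 miRNAs. The alternatives were the percentile over all probes, quantile normalisation, no scaling, a normexp background (offset of 50), the brightest probe, the software's total signal per miRNA, other filters on dim probes, only the first array of each mouse, all arrays with the mouse as a random block, the deposited value table, a trended and robust prior, a lower floor (0.001), other thresholds and leaving out each mouse in turn. The files held no mean spot signal, so normexp used the median signal and the median background. Scaling to 4 control RNAs, taken to be spiked in although the files do not say so, and a minimum of 30 signal units were added after seeing the data.

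The limma fit was tested on simulated miRNA values for the cold against room temperature comparison, in 20 sets of 189 miRNAs with 20 changed in each. Noise was independent between miRNAs, and the filter, scaling, floor and averaging of probes were not part of these sets. It recovered 17.2% of changes of 0.5 on the log2 scale, 81.5% of changes of 1 and 97% of changes of 2. Of the miRNAs it called in those sets, 9.21%, 4.12% and 3.72% were false. The number of arrays limits the precision of every value.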

Results

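miRNA levels were compared between brown adipose tissue of 3 mice kept at 8 °C for 24 h and of 3 mice kept at room temperature, on 8 arrays. Replicates were separate mice, and changes are log2 differences of cold minus room temperature, with the SE from limma. The room temperature arrays had 209 ± 15.3 mouse miRNAs well above background (SD, n = 3 mice), and the cold arrays differed from that by −27.3 on average (n = 3; exact permutation test, 2-sided, p = 0.1, the smallest that 3 mice against 3 allow). The 75th percentile of signal by which each array was scaled was 793 ± 149.7 units in the cold and 1085 ± 286 units at room temperature (SD, n = 3; exact permutation test, 2-sided, p = 0.2). Probes for 10 miRNAs of mouse viruses served as a background and averaged 1.37 ± 0.642 units in the cold and 0.758 ± 0.422 units at room temperature (SD, n = 3). The 2 arrays of mouse 1 correlated at r = 0.99 over miRNAs, and those of mouse 4 at r = 0.994. The spread between mice of a group was 1.45 times that between arrays of 1 mouse. The first principal component held 59.1% of the variance and separated the groups. The second held 22.5% and set mice 1 and 4 (3.11 and 3.48), the mice with 2 arrays each, apart from the other mice (−3.13 to −0.66). For these components the values were not scaled to equal variance per miRNA. miRNAs with a wide spread over the mice, among them the liver miRNA miR-122 and the muscle miRNAs, therefore weighed more.

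The main comparison asked which miRNAs of brown fat differ after 24 h of cold. The muscle miRNAs miR-133a, miR-133b, miR-133a* and miR-206 were 3.67-fold, 3.91-fold, 3.7-fold and 4.13-fold lower in the cold mice. The stromal miRNAs miR-199a-3p and miR-214, and miR-186 and miR-24-2*, were lower too. Higher in the cold mice were miR-378, which lies in an intron of the coactivator gene Ppargc1b, at 1.96-fold, the brown fat miRNA miR-193b at 1.55-fold, and miR-132, a miRNA induced through CREB, at 2.14-fold. With limma and Benjamini-Hochberg adjustment, 29 of the 189 miRNAs passed the threshold of 0.05, of which 16 were higher and 13 lower. An unadjusted p under 0.05 was met by 62. The cold and room temperature mice did not overlap for 73 miRNAs, among them all 29. Chance would give 10% of the 189, or 18.9, had the miRNAs been picked without regard to group. The filter instead kept probes well above background throughout either group, which favours separation, and miRNAs are not independent. The 73 therefore cannot be read as an excess over chance.

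These changes are relative to the 75th percentile of each array, and the balance of higher and lower calls moved with the scaling. The split was 11 higher and 17 lower with the percentile over all probes, 0 and 13 with no scaling, and 3 and 35 with scaling to the control RNAs, an alternative chosen after seeing the data. With no scaling the limma p followed the size of a change alone, so those 13 calls amount to a cut-off on that size. The median change of all miRNAs was −0.022 with the main scaling, −0.46 with none and −0.38 with the control RNAs. All 16 higher miRNAs kept a positive change under both of these scalings. The smallest main change among them, 0.56 for miR-188-5p, was larger than the shift that either scaling brings. The kept signs are therefore no separate evidence of a rise. Of the 16, 0 passed with no scaling and 3 with the control RNAs. Leaving out 1 mouse gave between 8 (without mouse 6) and 33 calls (without mouse 1). Of the 29 miRNAs, 6 passed whichever mouse was left out: miR-132, miR-186, miR-199a-3p, miR-24-2*, miR-34b-5p and miR-467b*. The probe filter was not redone in these fits. Of the 6, only miR-199a-3p was well above background on all 8 arrays and passed in every setting (highest limma adjusted p = 0.0475). In some setting the limma adjusted p reached 0.224 for miR-132, 0.692 for miR-186, 0.853 for miR-24-2*, 0.55 for miR-34b-5p and 0.223 for miR-467b*.

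**Figure D1:**
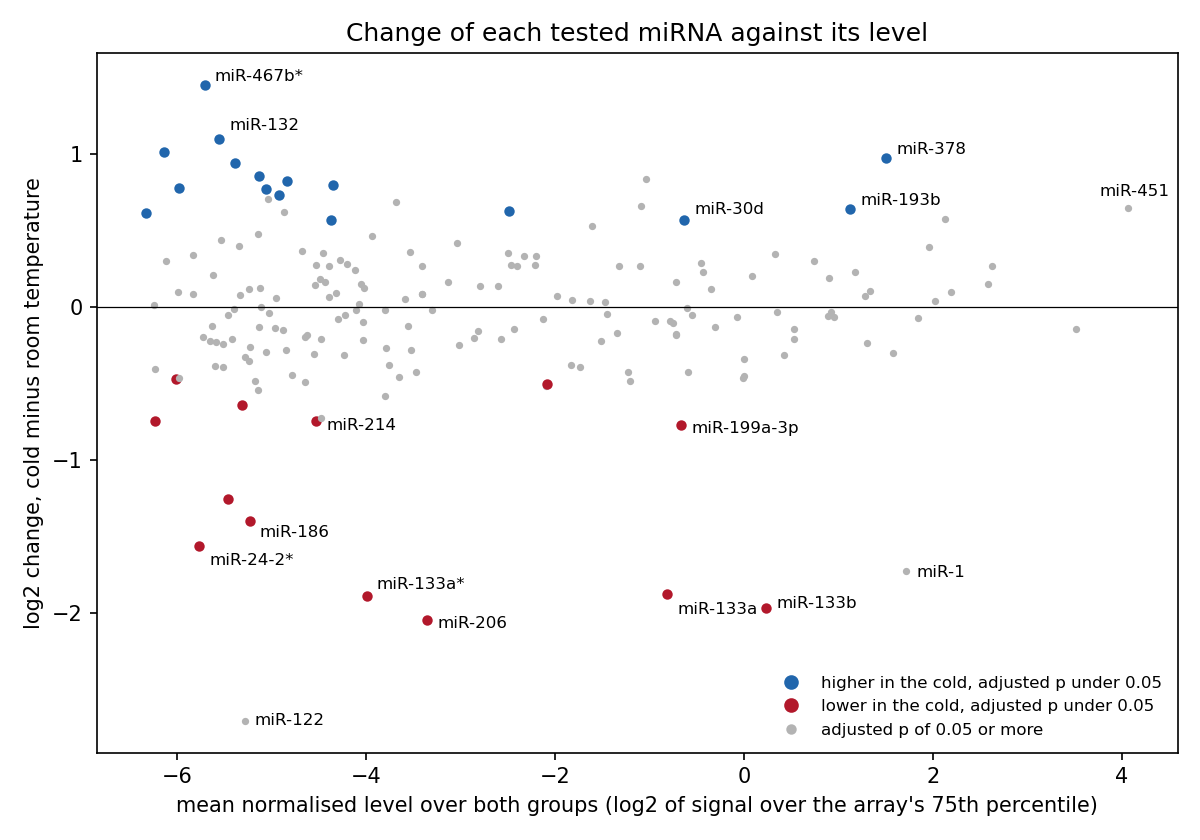
Each point is 1 of the 189 tested miRNAs, with its mean level over both groups on the x axis (log2 of signal over the array's 75th percentile) and its log2 change on the y axis (cold minus room temperature, 3 mice each). The 13 lower calls (red) reach −2.05 for miR-206 and the 16 higher calls (blue) reach 1.45 for miR-467b*, and most of the higher calls lie at the dim end of the x axis. The balance of higher and lower calls depends on the scaling.

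Of the miRNAs of striated muscle, 4 passed the threshold and were lower in the cold mice. miR-133a, which restrains myoblast and brown adipocyte differentiation, fell (−1.88 ± 0.444 on the log2 scale; SE, n = 3 mice per group; limma with Benjamini-Hochberg adjustment, adjusted p = 0.0229). miR-133b (−1.97 ± 0.461, SE, limma adjusted p = 0.0228), miR-133a* (−1.89 ± 0.435, SE, limma adjusted p = 0.0222) and miR-206 (−2.05 ± 0.553, SE, limma adjusted p = 0.0453), a skeletal muscle miRNA encoded beside miR-133b, fell as well. miR-1 differed by −1.73 ± 0.506 and missed the threshold (SE, limma adjusted p = 0.0549). In all 5, every cold mouse lay below every room temperature mouse. The normalised level of miR-133a was −0.62, −2.10 and −2.54 in the cold mice 1, 2 and 3, and 0.14, −0.12 and 0.35 in mice 4, 5 and 6. Among the 8 listed muscle miRNAs, 5 were measured, 3 of them fell, and 4 fell when adjusted over the list alone. The list includes miR-133a and miR-133b, which the study followed up from these samples, so its direction is not independent evidence. The list's mean change was −1.43, and camera gave an adjusted p of 0.157, or adjusted p = 0.662 with an estimated correlation. Its member miR-486, which is also abundant in erythroid cells, stood at 0.46. The slow-muscle miRNAs miR-499 and miR-208b, outside the tested set, were well above background on 3 room temperature arrays and on 0 cold arrays. miR-499 averaged 2.66 ± 3.1 units in the cold and 15.2 ± 7.72 units at room temperature (SD, n = 3; exact permutation test, 2-sided, p = 0.1). miR-208b averaged 0.298 ± 2.35 and 12.9 ± 6.89 units (SD, n = 3; exact permutation test, 2-sided, p = 0.1). The calls of miR-133a, miR-133b, miR-133a* and miR-206 held without mouse 1, where miR-206 stood at −2.71 and miR-1 passed too (−2.37, limma adjusted p = 0.000689). They were lost without any one of mice 2 to 6 (miR-133a −1.48 without mouse 3), where the limma adjusted p reached 0.108, 0.108, 0.101 and 0.145. They were also lost with the software's total signal per miRNA, and that of miR-206 with quantile normalisation (limma adjusted p = 0.0739). Over all alternatives, with those that leave out a mouse, the calls were lost 8, 8, 9 and 12 times for miR-133a, miR-133b, miR-133a* and miR-206. Over all settings the limma adjusted p of miR-133a ranged from 8.19e-09 with no scaling to 0.407 with no filter on dim probes. With no scaling p followed the size of the change alone. There miR-99b* at 0.821 and miR-340-5p at −0.821 both had a limma adjusted p of 0.125. The 8.19e-09 therefore does not measure the spread of miR-133a between mice.

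**Figure D2:**
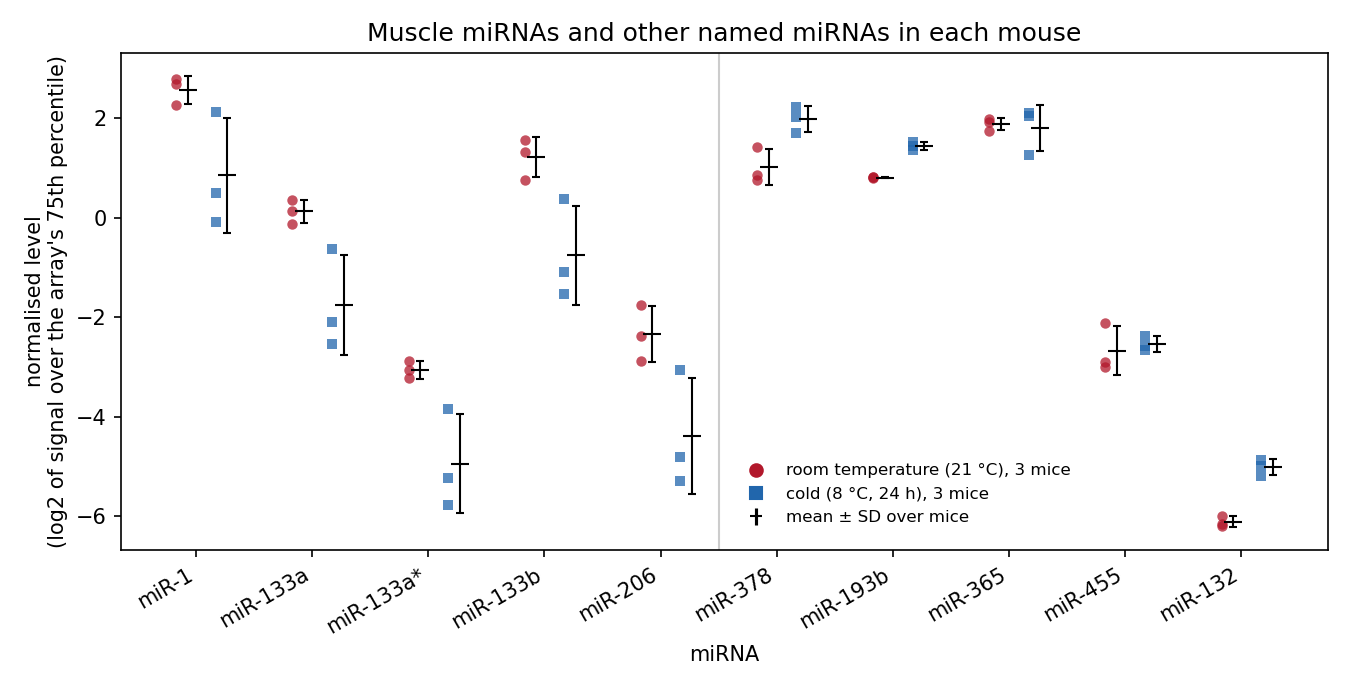
Each point is the normalised level of a miRNA in 1 mouse (log2 of signal over the array's 75th percentile; y axis), for 3 room temperature mice (red circles) and 3 cold mice (blue squares), with the mean ± SD of each group in black. For the 5 muscle miRNAs left of the grey line every cold mouse lies below every room temperature mouse. For miR-378 the cold mice lie between 1.71 and 2.22 and the room temperature mice between 0.76 and 1.42.

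Of 13 listed miRNAs that promote brown adipogenesis, 10 were measured, 2 rose and 8 did not pass, with the same count adjusted over the list alone. miR-378 rose by 0.97 ± 0.215 (SE, n = 3 mice per group; limma adjusted p = 0.0219), and its level was higher in 3 of 3 cold mice than in any room temperature mouse. miR-193b rose by 0.64 ± 0.117 (SE, limma adjusted p = 0.0129). With no scaling the changes were 0.53 for miR-378 and 0.20 for miR-193b, and neither passed. miR-378 passed without mouse 1 or mouse 6 only, and stood at 0.85, 0.95, 0.84 and 0.89 without mice 2, 3, 4 and 5 (limma adjusted p up to 0.0933). The call of miR-193b was lost without mouse 2 (0.60, limma adjusted p = 0.0552) and without mouse 6 (0.64, limma adjusted p = 0.059). miR-365, encoded beside miR-193b, differed by −0.07 ± 0.23 as the mean of 2 probes whose changes were −0.97 and 0.82. The brighter probe alone gave 0.82 (limma adjusted p = 0.0244, against up to 0.99 over the other settings). miR-455 stood at 0.13, miR-182 at 0.40, miR-203 at 0.42, miR-30b at −0.10 and miR-30c at −0.32, and none of them passed. The sign of miR-455 turned with no scaling and with scaling to the control RNAs, and those of miR-182 and miR-203 with no scaling. The list's mean change was 0.20, −0.24 with no scaling and −0.16 with the control RNAs (camera adjusted p = 0.249).

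All 14 listed miRNAs that restrain brown fat were measured, and 4 fell, 1 rose and 9 did not pass, also when adjusted over the list alone. Those that fell were miR-133a, miR-133b, miR-199a-3p (−0.77 ± 0.119, SE; limma adjusted p = 0.0105) and miR-214 (−0.75 ± 0.129, SE; limma adjusted p = 0.0121). miR-93, a miR-17 family member, rose by 0.62 ± 0.142 (SE, limma adjusted p = 0.0222) against the direction of these 4 calls. Of the 14, 5 had positive changes, among them miR-199a-5p at 0.68, and 9 had negative ones. The call of miR-214 was lost without mouse 6 (−0.68, limma adjusted p = 0.0544), and that of miR-93 without mice 2, 3, 5 and 6 (0.59, 0.55, 0.57 and 0.64). miR-155 stood at −0.08, miR-27a at −0.46, miR-27b at 0.35 and miR-34a at −0.17, and the sign of miR-27b turned with no scaling. The list's mean change was −0.33 (camera adjusted p = 0.236, or adjusted p = 0.662 with an estimated correlation; fry adjusted p = 0.049). All 4 that fell are also on the muscle list (miR-133a and miR-133b) or the stromal list (miR-199a-3p and miR-214), so the fall cannot be assigned to brown adipocytes, and the caution on miR-133 applies here too.

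Lists for other cell types of the tissue gave the following. Of 7 stromal and smooth muscle miRNAs, 5 were measured and 3 fell, also adjusted over the list alone: miR-199a-3p, miR-214 and miR-199b* (−0.50 ± 0.137, SE; limma adjusted p = 0.0453; lost without any one of mice 2 to 6, where it ranged from −0.58 to −0.44). miR-199a-5p stood at 0.68 and did not pass (0.29 without mouse 4, whose 2 arrays gave levels of −5.68 and −3.95). The list's mean was −0.37 (camera adjusted p = 0.157, or adjusted p = 0.662 with an estimated correlation; fry adjusted p = 0.00807). All 3 erythroid miRNAs had positive changes, miR-144 at 0.83, miR-451 at 0.64 and miR-486 at 0.46. None passed over all miRNAs, 2 passed adjusted over the list alone, and the camera adjusted p was 0.157. The list's mean of 0.65 was 0.205 with no scaling (miR-144 0.39, miR-451 0.20 and miR-486 0.021) and 0.29 with the control RNAs. The 7 leukocyte miRNAs all had negative changes, among them miR-142-5p at −0.55, miR-342-3p at −0.43 and miR-223 at −0.38, and none passed (list mean −0.32, or −0.755 with no scaling; camera adjusted p = 0.221). The 2 arms of the endothelial miR-126 stood at −0.15 and −0.29 without passing. Neural miRNAs gave 1 measured member, miR-128, at −0.49, which did not pass, and none of the 6 epithelial miRNAs was measured. The liver miRNA miR-122 had 1.74, 1.82 and −0.116 units in the cold mice, and 10.9, 259 and 119 units in the room temperature mice. It was well above background on 0 cold arrays, and its room temperature mean was at least 4.58-fold higher without passing (limma adjusted p = 0.115).

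**Figure D3:**
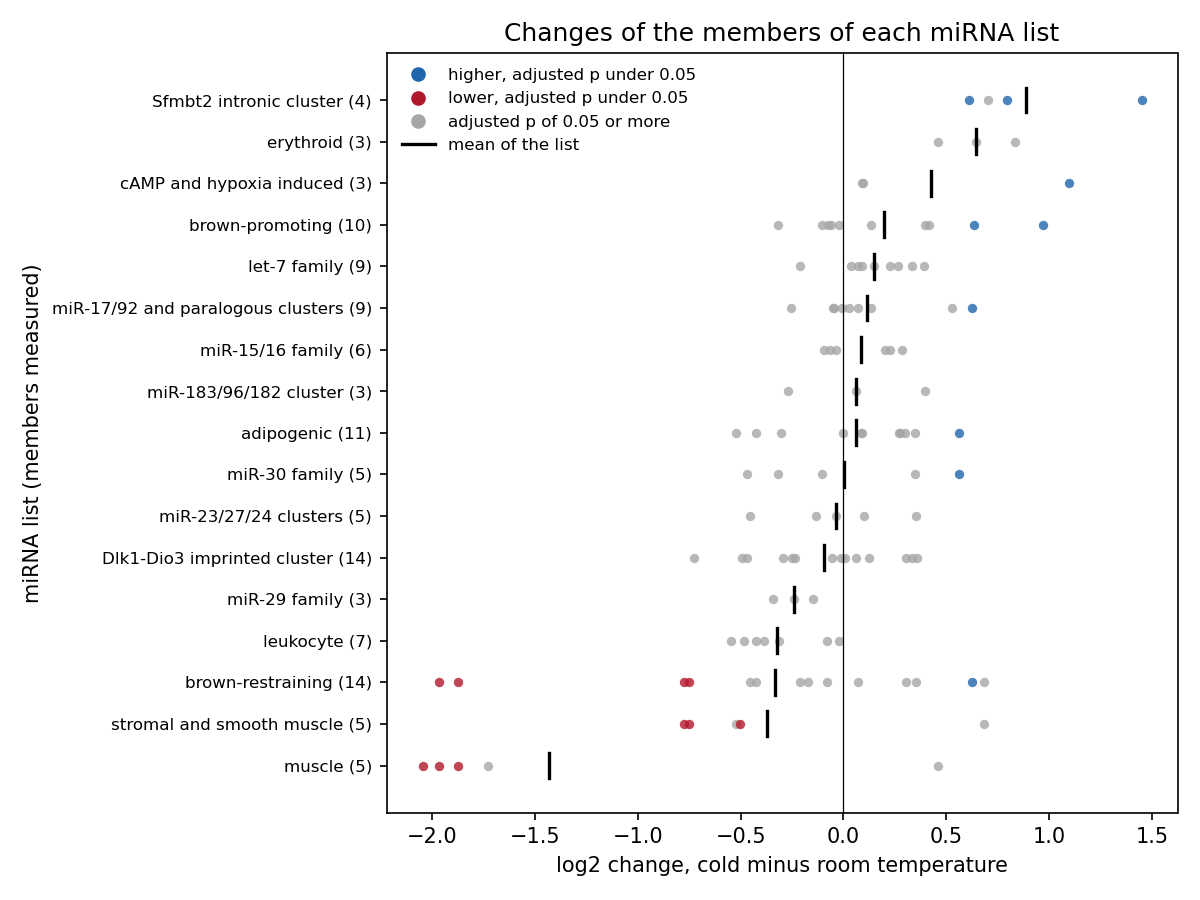
Each point is the log2 change (x axis, cold minus room temperature) of a measured member of the miRNA list named on the y axis, coloured where its adjusted p was under 0.05, and black bars give list means. Of the 17 lists shown, each with at least 3 measured members, the muscle list has the lowest mean, −1.43, and the Sfmbt2 intronic cluster the highest, 0.89. All list means are lower with no scaling (muscle −1.87, Sfmbt2 0.51), and those of the lists with small positive means turn negative.

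Among the other lists, the 3 miRNAs induced by cAMP or hypoxia held 1 that rose, also adjusted over the list alone. This was miR-132, which rose by 1.1 ± 0.138 (SE, n = 3 mice per group; limma adjusted p = 0.00362), while miR-212 from the neighbouring hairpin stood at 0.09 and the hypoxia miRNA miR-210 at 0.09. The signs of miR-212 and miR-210 turned with quantile normalisation, with no scaling and with the control RNAs. The camera adjusted p of the list was 0.236 (adjusted p = 0.662 with an estimated correlation), and that of fry 0.0435. In the Sfmbt2 intronic cluster, repeats of closely related hairpins in an imprinted gene, 45 members were listed. Of these, 21 were on the array and 4 were measured. Over all miRNAs 3 rose, and 4 did when adjusted over the list alone. miR-467b* rose by 1.45 ± 0.237 (SE, limma adjusted p = 0.0106), miR-466f-3p by 0.80 ± 0.172 (SE, limma adjusted p = 0.0205) and miR-467e* by 0.61 ± 0.125 (SE, limma adjusted p = 0.0192). The call of miR-466f-3p was lost without mice 3, 5 and 6 (0.77, 0.66 and 0.81), and that of miR-467e* without mice 2, 5 and 6 (0.61, 0.60 and 0.60). It was the 1 list past the threshold, with a mean change of 0.89 (camera adjusted p = 0.0106, but adjusted p = 0.662 with an estimated correlation). miR-467b* and miR-467e* were well above background on all 4 cold arrays but on 3 and 2 room temperature arrays. They thus passed the filter through the cold group, which favours a rise. Listed members outside the tested set went both ways in unscaled units. Lower in the cold were miR-467b (11.18, against 12.89 at room temperature), miR-467e (5.307 against 6.672) and miR-669a (8.475 against 11.4). miR-466c-5p was higher (8.404 against 7.96). The cold arrays were dimmer (75th percentile of 793 units, against 1085 at room temperature), and the rises given above are scaled for this. Under that scaling these untested members would stand higher in the cold than their unscaled units show. Their scaled directions were not computed. Of the room temperature mice, 1 for miR-467b* and 2 for miR-467e* lay at the floor, which sets the size of these changes in part. The 4 measured members were dim, with unscaled means of 31.3 units in the cold and 22.8 units at room temperature, and their probes can cross-hybridise.

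The remaining families moved little. In the miR-17/92 clusters 9 members were measured and miR-93 rose, while miR-92a stood at 0.53 and passed only adjusted over the list alone (mean 0.11, camera adjusted p = 0.517). Of 11 adipogenic miRNAs miR-30d rose, by 0.56 ± 0.123 (SE, limma adjusted p = 0.0205; lost without any one of mice 2 to 6, where it ranged from 0.50 to 0.60), while miR-107 stood at 0.30 and miR-148a at −0.42 (mean 0.061, camera adjusted p = 0.517). Of 5 miR-30 members miR-30d rose and miR-30e, at −0.47, passed only adjusted over the list alone, so that the list's mean was 0.0037 and its median −0.10 (camera adjusted p = 0.846). No member passed among the 9 let-7 miRNAs (mean 0.15, camera adjusted p = 0.249), the 3 of miR-29 (mean −0.24, adjusted p = 0.269) or the 6 of miR-15/16 (mean 0.086, adjusted p = 0.646). None passed among the 5 of miR-23/27/24 (mean −0.035, adjusted p = 0.846), the 3 of the miR-183 cluster (mean 0.063, adjusted p = 0.75) or the 14 measured of the Dlk1-Dio3 cluster (mean −0.096, adjusted p = 0.646). miR-221 was the 1 measured member of its pair, at 0.14. With no scaling and with the control RNAs the means of let-7, miR-15/16, miR-17/92, miR-30, the miR-183 cluster and the adipogenic list were negative. The 5 miRNAs with the highest normalised log2 mean over their probes, miR-451, miR-126-3p, let-7f, let-7a and let-7b, did not pass.

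Several of the largest changes were in dim miRNAs for which 1 group gives only a bound. miR-186, hosted by Zranb2, and miR-24-2* were well above background on all 4 room temperature arrays and on 0 cold arrays, and were at least 2.57-fold and at least 2.21-fold lower in the cold (limma adjusted p = 0.00167 and 0.0021). miR-34b-5p was at least 1.2-fold lower (limma adjusted p = 0.0106). miR-99b* was well above background on all 4 cold arrays and on 0 room temperature arrays, and was at least 1.92-fold higher (limma adjusted p = 0.0129), a call lost without mouse 2 or mouse 6 (limma adjusted p = 0.0564 and 0.0544). At the floor (−6.644) lay room temperature mice 4, 5 and 6 for miR-99b*, cold mice 1 and 2 for miR-24-2*, and cold mice 2 and 3 for miR-34b-5p. The floor hides the spread between these mice, which can make the limma p of these miRNAs too small. miR-29b* fell (−1.26 ± 0.271, SE, limma adjusted p = 0.0205), a call lost without any one of mice 2 to 5 (−1.16, −1.10, −1.11 and −1.17). Other dim miRNAs that rose were miR-467a-1*, whose precursor also lies in Sfmbt2 but whose name is not on the fixed list, by 0.94, miR-181d by 0.85, miR-574-3p by 0.82, miR-669n by 0.78 and miR-30c-1* by 0.77. All of these calls were lost without mouse 6 (0.88, 0.84, 0.78, 0.69 and 0.72, in that order). Further losses were of miR-467a-1* without mouse 5 (0.86), miR-574-3p without mice 2, 3 and 5 (0.89, 0.85 and 0.73) and miR-30c-1* without mice 2 and 5 (0.62 and 0.74). The 4 calls outside the naming rule, picked after their values were seen, were miR-193* at 0.73, miR-188-5p at 0.56, miR-24-1* at −0.64 and miR-340-5p, which was at least 1.25-fold lower. miR-188-5p passed in none of the fits with 1 mouse left out (0.49 to 0.64). miR-193* and miR-24-1* passed only without mouse 1 (otherwise 0.64 to 0.81 and −0.70 to −0.51), and miR-340-5p only without mouse 4 (limma adjusted p otherwise up to 0.176). With a minimum of 30 signal units, chosen after seeing the data, 9 miRNAs passed, 7 of them higher. With a normexp background, whose offset compresses dim signals, 6 miRNAs passed and miR-186, miR-24-2* and miR-214 stood at −0.10, −0.046 and −0.064. Of the miRNAs under the naming rule that were called, the sign turned there for miR-34b-5p (0.16) and miR-29b* (0.0015). The median change of all miRNAs was 0.207 with normexp, against −0.022 with the main processing, and the normexp values of these named miRNAs lie below it. The 4 calls outside that rule are not counted here.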

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

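The tests of the control RNAs in this part were chosen before their own results were seen, and the scaling to them only after the main result was seen. Outside the tested set, 44 miRNAs were well above background on at least 1 array. Of these, 1 (miR-468) was seen on a cold array and on no room temperature array, at a mean of 8.7 units in the cold and 5.63 units at room temperature, which set it apart as a signal in data the comparison did not use. In the other direction, 28 were seen on room temperature arrays and on no cold array, among them miR-499, miR-208b and miR-450b-3p.

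This goes with a lower miRNA signal on the cold arrays: the log2 of the 75th percentile was lower by −0.44 (SE 0.269, n = 3 mice per group). Weaker labelling or hybridisation would lower spiked-in RNAs by as much. The 4 control RNAs taken as such, which the files do not state, differed by −0.0857 (SE 0.181), which does not reach that drop, yet the SE is too wide to exclude it. Control probes of other kinds, left out because their role is not stated, went different ways. Every cold mouse was below every room temperature mouse for hur_1 (547 against 1006 units), hur_2 (12290 against 19230 units) and mr_1 (502 against 674 units). The mice overlapped for hur_4 (522 against 748 units) and hur_6 (1557 against 1683 units), and the bright corner spots averaged 23870 units in the cold and 18220 at room temperature. These probes decide nothing while their role is unknown. A lower share of miRNA in the RNA, through the cold itself or through RNA input, would lower the percentile relative to the control RNAs. That difference was −0.355 (SE 0.158), with every cold mouse below every room temperature mouse by a narrow margin (highest cold −2.12, lowest room temperature −2.10; exact permutation test, 2-sided, p = 0.1, the smallest possible with n = 3). If the 4 controls are spiked-in RNAs, fewer miRNAs in the RNA of the cold samples may account for part of the drop. Both explanations stay open, and the array row that holds the cold samples cannot be told apart from the cold.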

How the results depend on the processing

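Scaling to the control RNAs (called spiked-in below) and the minimum of 30 signal units were chosen only after the main result was seen. The count of changed miRNAs (29, with 16 higher and 13 lower) stayed within 1.5 times under the percentile over all probes, quantile normalisation, the brightest probe, total signal per miRNA, first arrays only, the mouse as a random block, a trended and robust prior, a lower floor and spiked-in scaling. The deposited table held the same values, so that alternative moved nothing. The count fell to 13 (0 higher) with no scaling, 6 (2 higher, 4 lower) with normexp, 5 (2 higher, 3 lower) with no filter on dim probes, 16 (10 higher, 6 lower) with probes detected on all 8 arrays, and 9 (7 higher, 2 lower) with at least 30 units. With no filter 566 miRNAs were tested, with the stricter filters 158 and 138. Spiked-in scaling gave 3 higher and 35 lower, and quantile normalisation 21 lower. A change of at least 1.5-fold left 25 (14 higher, 11 lower). An adjusted p under 0.10 took 46 (23 lower), and 73 (38 higher, 35 lower) had groups that did not overlap. Leaving out 1 mouse gave 8 to 33 in all, 3 to 19 higher and 5 to 14 lower. It gave 11 without mouse 2, 14 without mouse 3, 13 without mouse 5 and 8 without mouse 6. Of the other groupings of the 6 mice into 3 and 3, the highest gave 0 miRNAs against the real 29; as many arose in 1 of the 10 groupings, too few for a share under 0.05. For lists, 1 passed in the real grouping and up to 4 in others, with as many or more in 9 of the 10, which likewise cannot give a share under 0.05. The 1 list past the threshold became 0 with quantile normalisation, total signal per miRNA, at least 30 units or an estimated correlation, 2 with no scaling, 5 with normexp, 6 with no filter, 4 with fry and 8 with fry in either direction. It became 1 to 2 on leaving out a mouse. With probes detected on all 8 arrays 1 list passed, but it was the stromal list, lower, and the Sfmbt2 list lost its call. Named miRNAs kept direction and side in 792 values over the settings with all mice, while 94 lost the threshold, 38 gained it and 65 changed sign. With 1 mouse left out, 328 were kept, 64 lost, 7 gained and 9 changed sign. These changed sign with no scaling, none of them called: let-7a (−0.29), let-7b (−0.35), let-7c (−0.048), let-7f (−0.18), miR-107 (−0.14), miR-15a (−0.21), miR-15b (−0.15), miR-16 (−0.24), miR-182 (−0.043), miR-183 (−0.38), miR-203 (−0.023), miR-210 (−0.35), miR-212 (−0.24), miR-27b (−0.089), miR-30a (−0.094), miR-455 (−0.31), miR-495 (−0.10), miR-98 (−0.11), and the means of the brown-promoting (−0.24), let-7 (−0.29), miR-15/16 (−0.35), miR-17/92 (−0.33), miR-30 (−0.44), miR-183 cluster (−0.38) and adipogenic (−0.38) lists and of miR-221 (−0.30). With spiked-in scaling these did: let-7a (−0.21), let-7b (−0.26), let-7f (−0.091), miR-107 (−0.057), miR-15a (−0.13), miR-15b (−0.069), miR-16 (−0.15), miR-183 (−0.29), miR-210 (−0.27), miR-212 (−0.23), miR-27b (−0.0036), miR-30a (−0.0087), miR-455 (−0.22), miR-495 (−0.019), miR-98 (−0.022), and the means of the brown-promoting (−0.16), let-7 (−0.20), miR-15/16 (−0.27), miR-17/92 (−0.24), miR-30 (−0.35), miR-183 cluster (−0.29) and adipogenic (−0.29) lists and of miR-221 (−0.21). No scaling moves the changes by −0.44 and spiked-in scaling by −0.355, except for dim miRNAs near the floor, and these shifts turn small positive values. With the brightest probe these did, since probes of one miRNA differed: let-7b (−0.15), let-7f (−0.046), miR-126-3p (0.28), miR-203 (−0.14), miR-23b (0.10), miR-27b (−0.016), miR-29a (0.18), miR-29c (0.26), miR-30a (−0.25), miR-30c (0.068), miR-365 (0.82) and miR-96 (0.22). With total signal per miRNA these did: let-7b (−0.020), let-7f (−0.0082), miR-126-3p (0.060), miR-155 (0.13) and miR-30c (0.15). With normexp these did among the miRNAs under the naming rule, 2 of them called in the main test: miR-29b* (0.0015), miR-34b-5p (0.16), miR-142-5p (0.14), miR-155 (0.19), miR-411 (0.23) and miR-96 (0.084). Calls outside that rule are not counted here. The median change of all miRNAs was 0.207 with normexp. Smaller sets turned with no filter (miR-155, 0.25), first arrays only (miR-155, 0.013, and miR-212, −0.018), probes detected on all 8 arrays (miR-203, −0.14, and miR-96, 0.22), the percentile over all probes (miR-183, −0.012) and quantile normalisation (miR-210, −0.0067, miR-212, −0.0092, and miR-30b, 0.0077). Leaving out a mouse turned miR-155 (0.036 without mouse 3), miR-183 (−0.22, −0.0047, −0.18 and −0.11 without mice 1, 2, 5 and 6, range −0.22 to 0.48), miR-30b (0.46 and 0.17 without mice 1 and 6, range −0.51 to 0.46), miR-365 (0.19 without mouse 1) and miR-455 (−0.038 without mouse 4, range −0.038 to 0.41). Other causes were not tested. The number of detected miRNAs was lower in the cold by −21.3 with the software's own flag and by −27.3 in the main measure, and the ratio of mouse to technical spread stayed at 1.46 with no filter. No paired analysis was run because the groups share no mouse numbers, and no slide or scan block was run because there was 1 slide and 1 scan. Position within a slide row was not used as a block, so effects of position shared by mice of both groups were not tested. Signal near background limits the dim miRNAs.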

Other observations

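The muscle and Sfmbt2 tests in this part were chosen only after the result was seen, and so was the demand that both arm correlations pass; the arm and neighbour tests were chosen before. The 2 arms under one miRNA name had like values for miR-133a (−1.88 and −1.89) and miR-193 (0.66 and 0.73). They had less alike values for miR-378 and miR-378* (0.97 and 0.11), and miR-29b and miR-29b* (−0.15 and −1.26). The values of miR-199a-3p and miR-199a-5p had opposite signs (−0.77 and 0.68), the latter moving to 0.29 without mouse 4. These pairs were picked after their values were seen, and no difference between arms was tested. The names miR-133a, miR-29b and miR-199a each have 2 precursor genes, so their pairs do not compare the arms of a single hairpin. Over 20 pairs, 13 had changes of the same sign. Pearson's r across these pairs was 0.543 (permutation p = 0.0179) and Spearman's rho 0.317 (permutation p = 0.171), 2 measures of 1 relation. Without the 2 pairs farthest from the median r was 0.193, and without miR-133a 0.189, so the relation rests on miR-133a. miRNAs are not independent replicates.

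miRNAs whose precursor genes lie within 10000 bases of each other in GRCm38.p6 differed in their changes by 0.47 on average over 70 pairs, against 0.535 when changes were shuffled (1-sided permutation p = 0.2), which leaves open whether neighbours moved together. The muscle pair miR-133b and miR-206 share a neighbourhood. miR-93 (0.62) shares one, inside Mcm7, with miR-106b (0.069) and miR-25 (−0.047). miR-132 (1.1) shares one with miR-212 (0.093). miR-193b (0.64) lies beside 1 of the 2 precursor genes of miR-365, whose brighter probe stood at 0.82 and whose other probe at −0.97. The hypothesis that miR-193b and miR-365 rose together may hold for the brighter probe, and the other probe goes against it.

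The 4 muscle miRNAs that fell and miR-1, which did not pass, had like changes, which spanned 0.32 on the log2 scale, under the 0.922 of 2 median SE, and their deviations from the group means went together over the mice (lowest pairwise r 0.916, over 6 mice centred by group). A lower share of adjoining skeletal muscle in the cold samples predicts this, and it is a candidate explanation, as are the levels of miR-499 and miR-208b, which the room temperature mice had at 15.2 and 12.9 units. Lower levels in the brown adipocytes of cold mice would also put all cold mice below all room temperature mice, as was seen for 5 of the 5, and the arrays hold no value that decides between these explanations. The 5 are not independent readouts. miR-133a* shares its precursor genes with miR-133a, those of miR-1 lie beside them, and miR-206 lies beside miR-133b. Like changes that go together could therefore arise under either explanation, and their likeness favours neither. Mouse 1 lay between the other cold mice and the room temperature mice, with a mean level over the 5 of −1, against −2.79 in mice 2 and 3 and −0.29 in the room temperature mice. Muscle messenger RNAs, which would bear on this, were not analysed here.

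For the Sfmbt2 cluster, signal that does not depend on RNA could rise through the scaling of the dimmer cold arrays. Without scaling the 4 members still averaged 0.509 above room temperature (SE 0.178 over members, 0.209 between mice), from 0.264 to 1.04 (miR-467b*). The members are related, so the SE over members is not one of independent replicates. miR-467b* and miR-467e* also passed the filter through the cold group, which favours a rise. The value therefore does not decide whether scaling was the cause. Higher unspecific signal in the slide row of the cold samples would raise negative control spots. These differed by 0.036 units (SE 0.281), against a rise of 8.45 units in the members. Viral probes averaged 1.37 units in the cold and 0.758 units at room temperature. Both argue against a general rise of unspecific signal of that size. Neither measures unspecific signal that depends on the members' own sequences, so an effect of the slide row on them stays open. A rise with the cold stays open as a hypothesis, as does cross-hybridisation among related probes, which was not tested.

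The liver miRNA miR-122 reached 259 and 119 units in room temperature mice 5 and 6, against 10.9 units in mouse 4.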
